A study of Oryctolagus cuniculus with 4 samples.

How the data were processed

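RNA from rabbit tendon stem/progenitor cells was sequenced after culture in medium with 10% (v/v) platelet-rich plasma (PRP), a concentrate of platelets in plasma that carries growth factors, or in medium without it (noPRP). Each group held 2 libraries. Per the labels' protocols, total RNA was extracted with TRIzol, messenger RNA was purified on magnetic beads, and libraries were made with an Illumina TruSeq RNA kit and read on a HiSeq instrument. The labels do not say whether the 2 libraries of a group came from separate animals or cultures. The p-values therefore rest only on the spread between these libraries, taken over many genes, and that spread may be technical.

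The deposited values were raw read counts per gene, 1 table per library. Per the submitters' processing notes, STAR 2.7.2a and featureCounts 1.6.5 were used with the OryCun2.0 rabbit genome. Per the file headers, the counts were summed over the exons of each gene of Ensembl release 98, with no option for strand, read pairs, reads with several alignments or overlapping genes. By the program's defaults the reads were therefore counted without regard to strand, the ends of a pair were counted separately, and reads with several alignments or on overlapping genes were dropped. Even counts were in excess among low values: in noPRP replicate 1, 634 genes had a count of 1, 1042 a count of 2, 310 a count of 3 and 520 a count of 4. Members of multigene families and antisense genes are uncertain under such counting. The table of the whole series held values equal to those of the library tables in every column (0 columns differed), so it gave no separate result.

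The tables listed 29587 Ensembl gene identifiers with their exon positions and no gene symbols. The gene table used here for names came from another rabbit assembly and matched 0 of these identifiers, so the files and that table do not pair identifiers with names. Of the 26 gene lists fixed before the data were examined, only the mitochondrially encoded genes could be tested, taken as all genes on the mitochondrial sequence. The fixed list held only protein-coding and ribosomal RNA genes, which the files do not name, so the genes of at least 200 bases were also tested alone, an alternative added after the data were examined. The other lists, which covered tendon, inflammation, matrix turnover, proliferation, growth factor response and other cell types, have no result here, nor have the single genes fixed beforehand.

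Total counts were 20100175 and 20947284 in the noPRP libraries and 24064713 and 23829027 in the PRP libraries. Genes were kept by edgeR's filterByExpr function, which left 12707 genes that held 99.92% to 99.94% of each library's counts. Normalization was by the trimmed mean of M values (TMM), with factors of 1.09, 1.09, 1.00 and 0.842 in the same order of libraries. The groups were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with the group as the only term, and p-values were adjusted by Benjamini-Hochberg over all tested genes. Genes with an adjusted p under 0.05 are called rising or falling in PRP. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Each gene had 2 residual degrees of freedom, and a median of 11.4 prior degrees of freedom was drawn from the other genes. At the median, the error term thus rested more on other genes than on the gene's own libraries. An exact permutation test of 2 against 2 libraries cannot give a two-sided p under 0.333. The mitochondrial set was tested with camera in limma 3.58.1 (two-sided, preset correlation 0.01, then an estimated one) and with fry.

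The rule for named genes took the 10 rising and 10 falling genes with the largest fold change among those past 5%, with a symbol, an average log2 counts-per-million (CPM) of at least 1 and both PRP libraries on the same side of both noPRP libraries. The condition on symbols could not be met. The rest of the rule was applied, and the top 2 identifiers in each direction are printed. Other genes and regions are given by position in OryCun2.0 and were chosen after their values were seen. A fold against a group at 0 was computed against a floor of 3 counts summed over that group. Shares of counts have 95% Wilson intervals; intervals and floors cover counting error only.

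Called genes of one direction were put in the same neighbour group when the gap between them on a sequence was at most 500 kb, and the number of grouped genes was compared with 10000 random draws from the tested genes (one-sided). Chromosomes were compared with camera over a family of 24 sets. Both of these analyses were chosen after the data were examined.

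The statistical steps were tested on simulated data. Counts for 12707 genes were drawn from the real means and library sizes, and 50 genes at each of 4 fold sizes were changed. Of these, 0 were recovered at 2-fold, 2 at 4-fold, 20 at 16-fold and 48 at 64-fold, with 0 false calls among 70. Each gene was drawn independently, with the dispersion of the fitted trend. The simulated data thus held no dispersion particular to a gene and no difference shared between genes. Recovery and false calls in the real libraries may therefore differ.

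Alternatives fixed beforehand were the size factors of DESeq2, upper-quartile normalization, no filter, a filter of at least 50 counts in 2 libraries, DESeq2 1.42.0 and limma-voom as tests, a replicate block, glmTreat against a log2 fold change of 1, and each library left out in turn. Alternatives added after the data were examined were a crossed pairing of replicates, other gaps between neighbours and offsets for a regional trend. For the offsets, each gene was given the median within-group difference of up to 10 tested neighbours on each side, which 12048 genes had, and each library's deviation along that value was removed by loess.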

Results

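Messenger RNA was measured in cultured rabbit tendon stem/progenitor cells, the cells of tendon that can divide and form new tendon cells. The study used 2 libraries from cells grown without PRP and 2 from cells grown with 10% (v/v) PRP. The noPRP libraries held 20100175 and 20947284 counted reads, and the PRP libraries held 24064713 and 23829027. Between 15796 and 17499 of the 29587 listed genes had at least 1 count in a library. The single comparison of the design asks which transcripts differ between cells cultured with and without PRP.

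A small set of genes differed by large factors between the groups. Of 12707 tested genes, 68 were higher and 41 were lower in PRP at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). The fitted change of each of the 109 genes exceeded 2-fold, and with genes at 0 in a group set to their bound the median log2 fold change was 6.22 for the rising and −5.63 for the falling genes. Of the rising genes, 15 had 0 counts in both noPRP libraries, and 3 of the falling genes had 0 counts in both PRP libraries. Over all listed genes, 34 had 0 counts in both noPRP libraries and at least 10 in both PRP libraries, against 9 with the opposite pattern. At an unadjusted p under 0.05, 1693 genes differed. In the simulated data, drawn independently for each gene, the same edgeR fit recovered 0 of 50 changes of 2-fold, 2 of 50 of 4-fold and 20 of 50 of 16-fold. Upper-quartile normalization gave 46 rising and 14 falling genes, which moved the rising share from 62.4% to 76.7%. The balance turned to mostly falling genes with DESeq2 (306 rising, 422 falling), without a filter (230 and 335) and without noPRP replicate 1 (138 and 433). Without PRP replicate 1 there were 165 called genes, with the lone library assumed to vary like the other group.

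**Figure D1:**
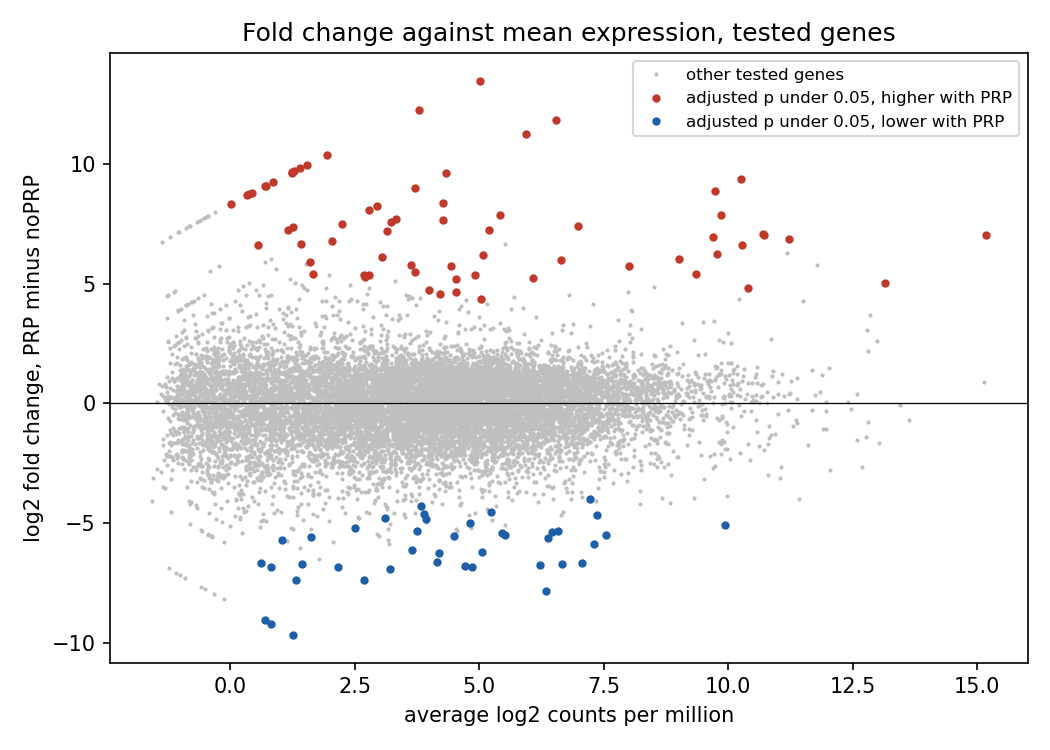
Log2 fold change (PRP minus noPRP) against average log2 counts-per-million (CPM) for the tested genes, 1 point per gene. The 68 rising genes (red) and 41 falling genes (blue) lie among the largest fold changes over most of the range of expression, and the straight rows of points at the left are genes with 0 counts in a group.

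The rising genes took up a large part of the PRP transcript pool. Together they held 0.141% (95% Wilson interval 0.139 to 0.1423) and 0.171% (0.1689 to 0.1724) of the counts in noPRP replicates 1 and 2. In the PRP libraries they held 13.7% (13.67 to 13.7) and 8.92% (8.911 to 8.934), so the group means were 0.156% ± 0.021 and 11.3% ± 3.4 (SD, n = 2 each). The falling genes held 0.29% (0.288 to 0.2927) and 0.863% (0.8591 to 0.8671) of the noPRP counts. Their share of the PRP counts was 0.0184% (0.01783 to 0.01891) and 0.0075% (0.007164 to 0.007859). These genes were selected for their difference, so the shares describe its size and are not a further test.

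**Figure D2:**
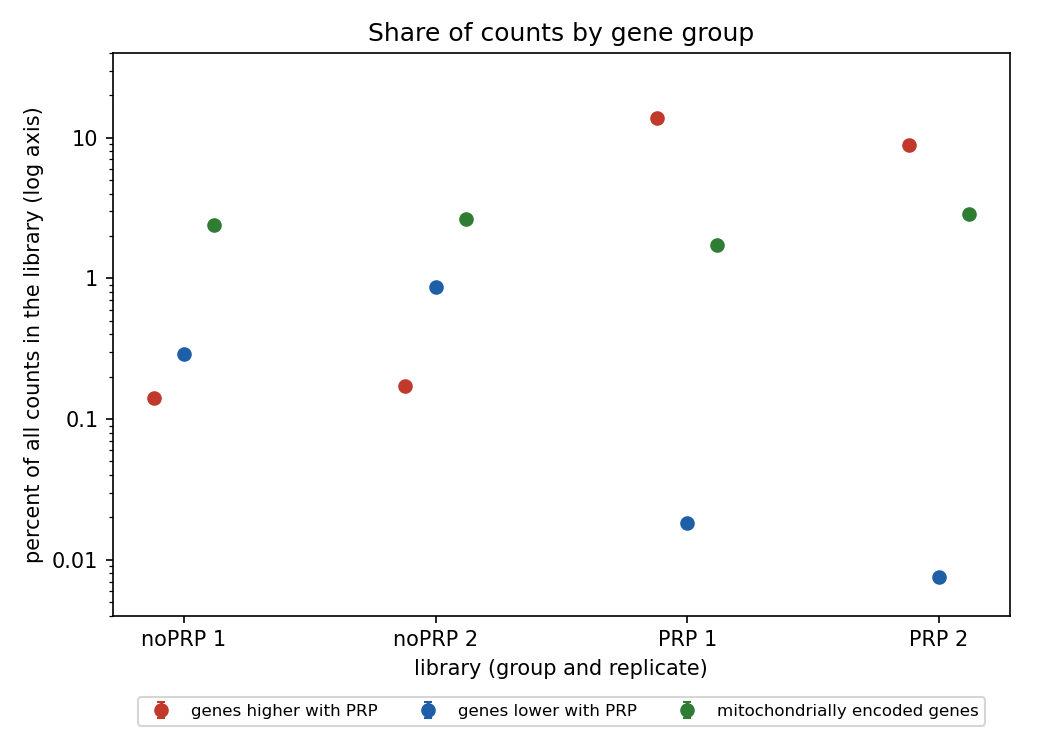
Percent of all counts (log axis) held by the rising, falling and mitochondrially encoded genes in each library, with 95% Wilson intervals smaller than the points. The rising genes lie at 0.141% and 0.171% in noPRP and at 13.7% and 8.92% in PRP, while the mitochondrial genes lie between 1.72% and 2.88% in the 4 libraries.

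Most of this share came from 1 gene on the unplaced sequence GL018733, at positions 2135282 to 2139361, with 4 exons and an exon length of 554 bases. It was at 553 ± 320 CPM in noPRP and 73400 ± 12000 CPM in PRP (SD, n = 2 each), a log2 fold change of 7.05 (SE 1.18, edgeR adjusted p = 0.021). It accounted for 8.18% and 5.46% of the counts in PRP replicates 1 and 2, against 0.0357% and 0.0846% in the noPRP libraries. The next most abundant called gene, on chromosome 16 at positions 68595451 to 68601787, was at 538 ± 190 CPM in noPRP and 17600 ± 5400 CPM in PRP (SD, n = 2 each). Its log2 fold change was 5.03 (SE 1.0, edgeR adjusted p = 0.0367). Among the falling genes, the most abundant lay on chromosome 13 at positions 61054286 to 61261797 and had 68 exons. It was at 1910 ± 1400 CPM in noPRP and 56.3 ± 43 CPM in PRP (SD, n = 2 each), with a log2 fold change of −5.08 (SE 1.06, edgeR adjusted p = 0.0418).

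The 2 identifiers at the top of the rising genes had 0 counts in noPRP. ENSOCUG00000007233, with 4 exons on chromosome 4 at positions 39915179 to 39916220, had 0 counts in both noPRP libraries and 1958 and 961 in the PRP libraries. This is at least 986-fold higher, from a floor of 3 counts over the noPRP group (edgeR adjusted p = 0.00467). ENSOCUG00000004161, with 5 exons on chromosome 2 at positions 97865546 to 97881097, had 0 counts in both noPRP libraries and 350 and 813 in PRP, at least 393-fold higher (edgeR adjusted p = 0.00965). Both passed under all 13 alternatives in which they were tested, with adjusted p up to 0.0147 and 0.0223. With each library left out in turn, the bound lay between 485 (without noPRP replicate 2) and 1210 (without PRP replicate 2) for the former and between 193 (without noPRP replicate 2) and 604 (without PRP replicate 1) for the latter. Leaving out a noPRP library changes only the floor, because both were at 0, so the lower ends show no change in the genes.

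The calls of the 2 identifiers at the top of the falling genes depended on the processing. ENSOCUG00000003052, with 6 exons on the unplaced sequence GL018714 at positions 2650421 to 2807619, had 22 and 187 counts in the noPRP libraries and 0 in both PRP libraries. This is at least 68.7-fold lower, from a floor of 3 counts over the PRP group (edgeR adjusted p = 0.0383). ENSOCUG00000002481, with 10 exons on chromosome 1 at positions 113615791 to 113627810, had 152 and 7139 counts in noPRP and 20 and 11 in PRP, a log2 fold change of −7.85 (SE 1.56, edgeR adjusted p = 0.0367). Without noPRP replicate 2 the former was at least 14.7-fold lower (adjusted p = 0.166), and without PRP replicate 1 or PRP replicate 2, which changes the floor, at least 31.3-fold and 37.5-fold lower; without noPRP replicate 1 it was at least 121-fold lower. The log2 fold change of the latter was −3.32 without noPRP replicate 2 (adjusted p = 0.366) and −8.80 without noPRP replicate 1. Both also missed 5% with upper-quartile normalization (adjusted p = 0.0594 and 0.0584) and with regional offsets (0.0833 and 0.0808), where their fitted log2 fold changes stayed large, at −9.67 and −7.83 with the normalization and at −9.77 and −6.57 with the offsets. With limma-voom the latter gene had a log2 fold change of −6.06 (adjusted p = 0.13), and with a replicate block −6.07 (edgeR adjusted p = 0.14). Of its 13 alternatives, 8 kept the call. Over all alternatives the adjusted p ranged from 4.6e-08 to 0.166 and from 2.47e-17 to 0.366.

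Many rising genes were neighbours in the genome. Of the 68, 31 lay within 500 kb of another rising gene, in 11 groups, against a median of 4 and a highest value of 16 in 10000 random draws (one-sided permutation p = 1e-04, the smallest these draws can give). Of the 41 falling genes, 2 lay in 1 such group (p = 0.5, same permutation test). The group with the most members spanned positions 97560400 to 98003751 of chromosome 2, where 6 of the 7 tested genes rose, with log2 fold changes of 5.97 to 12.26. Their summed level was 15.6 and 22.0 CPM in the noPRP libraries and 1910 and 1000 CPM in the PRP libraries, of which 1 gene held 57.4% to 93.2%; the other 5 together were at 5.01 and 1.5 CPM and at 445 and 427 CPM. On GL018733, 4 of 7 tested genes between positions 1737136 and 2191252 rose. The abundant gene already described held 97.4% to 99.4% of their summed level in each library, and the other 3 together went from 2.82 and 4.62 CPM to 2150 and 1310 CPM. On chromosome 13, all 3 tested genes between positions 39004122 and 39034219 rose, from 31.3 and 87.4 CPM to 4960 and 9280 CPM. On chromosome 16, all 3 tested genes that lay within positions 68559446 to 68612080 rose. The abundant gene already described held nearly all of their counts, and the other 2 together had 0 counts in both noPRP libraries and 89 and 124 in the PRP libraries. Among as many genes with the largest differences between the 2 noPRP libraries, 10 in one direction and 16 in the other lay in groups. The random draws took genes independently and so held no such difference shared by neighbours. With upper-quartile normalization 16 of 46 rising genes were grouped, and with regional offsets 19 of 53, against at most 10 in 1000 random draws for each; without noPRP replicate 1, 49 of 138 were grouped against at most 28.

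**Figure D3:**
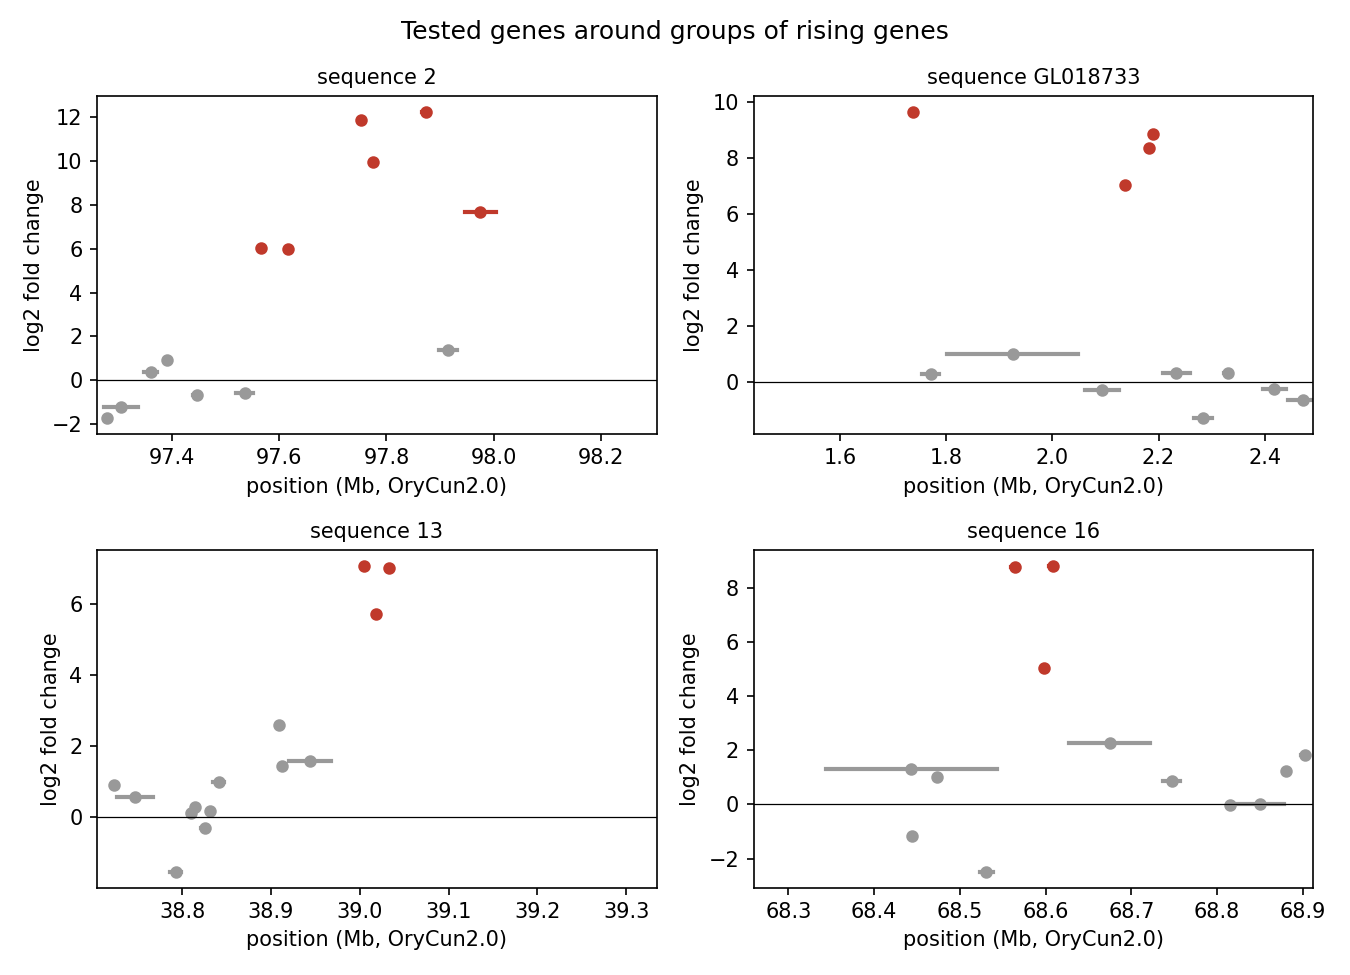
Log2 fold change (PRP minus noPRP) of the tested genes against position in Mb around the 4 groups of neighbouring rising genes on chromosomes 2, 13 and 16 and the unplaced sequence GL018733; bars span each gene. Rising genes are red and other tested genes grey; the 6 rising genes on chromosome 2 lie between 5.97 and 12.26, above the other tested genes of the stretch.

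Fold changes of genes that did not pass the test also followed their position. Across the 12598 genes that did not pass, the log2 fold changes of adjacent genes had a Spearman rho of 0.432 over 11023 pairs (0.438 over all tested genes), and the highest value in 1000 shuffles was 0.029 (permutation p = 0.001, the smallest possible); genes are not independent replicates. For these genes the median log2 fold change was 0.66 on unplaced sequences (3380 genes), 0.61 on chromosome 6 and 0.40 on chromosome 19. It was −0.85 on chromosome 15, −0.82 on chromosome 11 and −0.73 on the X chromosome. Over all tested genes, with camera's preset correlation, the adjusted p over 24 sets was 1.52e-06 for unplaced sequences and 2.62e-05 for chromosomes 11 and 15; with an estimated correlation each of the 3 had an adjusted p = 0.538. The same chromosomes separated libraries within a group: the median of noPRP replicate 1 minus noPRP replicate 2 was 0.74 on unplaced sequences and −0.90 on chromosome 15, and that of PRP replicate 2 minus PRP replicate 1 was 0.37 and −0.60.

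**Figure D4:**
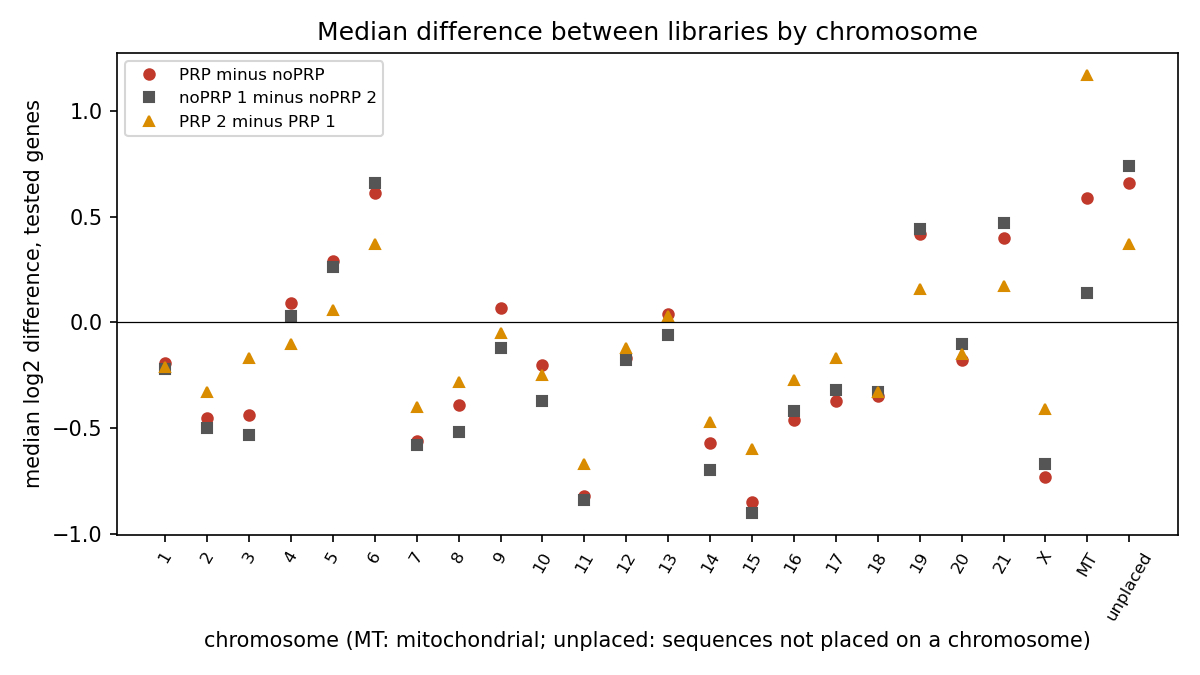
Median log2 difference of the tested genes on each chromosome for PRP minus noPRP (circles), noPRP replicate 1 minus noPRP replicate 2 (squares) and PRP replicate 2 minus PRP replicate 1 (triangles). The 3 medians for chromosome 15 are −0.85, −0.90 and −0.60, and those for unplaced sequences are 0.66, 0.74 and 0.37.

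The mitochondrially encoded genes, which code for parts of the respiratory chain and for its translation, held 2.53% ± 0.18 of the noPRP counts and 2.30% ± 0.82 of the PRP counts (SD, n = 2 each). Of 37 listed genes, 33 were tested and 0 passed the 5% threshold in edgeR, both over all genes tested and adjusted over the list alone, with 2 at an unadjusted p under 0.05. Fold changes were positive for 27 and negative for 6, with a median log2 fold change of 0.59. The median was 0.31 for the 15 genes of at least 200 bases and 0.81 for the 18 genes of up to 75 bases, a class that the list fixed beforehand did not hold. The set passed with camera's preset correlation (p = 0.0396) and did not with an estimated one (p = 0.671), and fry gave p = 0.486. With only the 15 longer genes it did not pass either way (camera p = 0.543, and p = 0.869 with an estimated correlation). Without PRP replicate 2 the median was −0.19, and without PRP replicate 1 it was 1.10.

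The groups did not separate the libraries by rank correlation over all tested genes. Across these genes, Spearman's rho of log2 CPM was 0.871 between the noPRP libraries and 0.902 between the PRP libraries. Between groups, it was 0.908 for noPRP replicate 1 with PRP replicate 1, 0.877 for noPRP replicate 1 with PRP replicate 2, 0.820 for noPRP replicate 2 with PRP replicate 1, and 0.654 for noPRP replicate 2 with PRP replicate 2. Pearson's r of noPRP replicate 1 was 0.878 with noPRP replicate 2, 0.882 with PRP replicate 1 and 0.863 with PRP replicate 2. Between the PRP libraries it was 0.897, the highest of all pairs. For noPRP replicate 2 it was 0.81 with PRP replicate 1 and 0.658 with PRP replicate 2. The common biological coefficient of variation was 0.605. The counts of library pairs within a group differed far beyond sampling noise, with a chi-square per degree of freedom of 477 for noPRP and 373 for PRP, so no pair was 1 library deposited again; this does not tell separate cultures from repeat preparations of 1 culture. Of the tested genes, 46.9% had groups that did not overlap, where chance gives 33.3% if the libraries are exchangeable. The other 2 splits of the libraries into pairs gave 41.9% (noPRP replicate 1 with PRP replicate 2) and 11.2% (noPRP replicate 1 with PRP replicate 1).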

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

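PRP replicate 2 had counts for 1752 genes that were at 0 in the other 3 libraries, against 488 and 516 such genes in the noPRP libraries and 503 in PRP replicate 1. None of the 1752 was among the tested genes; together they held 3920 counts, with at most 18 on a gene. A greater depth is argued against, since after all libraries were thinned to 20100175 counts PRP replicate 2 still had 1392 more genes with a count than the highest other library. Reads from genomic DNA remain a possible explanation that these counts do not decide: read pairs on genes of 1000 to 2000 bases at 0 elsewhere had a variance of 1.6 times the mean, above the limit of 1.5 set beforehand for random scatter and below the 2 that would have spoken against it. The other libraries had 1.76, 1.69 and 1.59, so this value does not set PRP replicate 2 apart. Read pairs per kilobase differed by 3.65 times between length classes of all genes at 0 elsewhere, past the limit of 3 set beforehand against genomic DNA. That limit left out that a read needs to overlap an exon only in part, so short genes collect more per kilobase. Exons were therefore extended for assumed reads of 100 or 150 bases (the length is not given in the sources used here). The ratio was then 2.54 or 2.28, still above the 1.5 set beforehand for even coverage. Among the classes above 1000 bases, without extension, it was 1.38, within that 1.5. The extension and the restriction to longer genes were not set beforehand and gave ratios on both sides of 1.5, so the explanation is left open and not favoured. An effect of PRP was not tested on these genes, which are at 0 in PRP replicate 1 by their selection, nor was RNA of other cells, because the identifiers carry no names.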

How the results depend on the processing

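The crossed pairing, the regional offsets, the other gaps between neighbours and the longer mitochondrial genes alone were chosen after the data were examined. In each of the 13 other fits the 109 genes, where tested, kept the sign of their fold change, while their calls varied. All 109 had groups that did not overlap and log2 fold changes of at least 4.01 in size. A kept sign was therefore nearly fixed by their selection and is no further support. The number of called genes was 109 in the main analysis, and it was 60 with upper-quartile normalization (14 falling), 565 without a filter (230 rising, 335 falling), 728 with DESeq2 (306 rising, 422 falling) and 65 with regional offsets (12 falling); all passed 2-fold. It lay within 1.5 times of 109 with DESeq2's size factors, the stricter filter and limma-voom. The test against a 2-fold minimum left 68 genes. DESeq2 and the unfiltered fit, which called many more genes, called all 109 genes again, as did DESeq2's size factors. The offsets called 58 of them again (46 of 68 rising, 12 of 41 falling). Upper-quartile normalization kept 46 rising and 14 falling genes, limma-voom 68 and 33, and the stricter filter 60 and 35. Falling calls were thus kept less often than rising ones with the offsets, upper-quartile normalization and limma-voom. Leaving out a library gave 114 to 571 called genes, with 75 to 138 rising and 29 to 433 falling, the highest without noPRP replicate 1. Rising genes in neighbour groups, 31 in the main analysis, numbered 16 with upper-quartile normalization, 96 without a filter, 133 with DESeq2, 19 with offsets and 31 to 49 without a library; gaps of 100 and 1000 kb gave 30 and 32. The cause of these shifts was not tested.

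The replicate numbers were not said to pair samples, and deviations from the group means of same-numbered libraries had a correlation of −0.63 across genes. With a replicate block 57 genes were called (46 rising, 11 falling), 55 of them among the 109, 21 rising genes were grouped, and the mitochondrial median of 0.49 did not pass camera. A crossed pairing called 3588 genes (1652 rising, 1936 falling), including all 109. No label gives this pairing, which was chosen after the data were examined and joins libraries whose deviations were alike. It lowered the common biological coefficient of variation from 0.605 to 0.364, so its larger number of calls is no further support.

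The mitochondrial median of 0.595 passed camera in 4 of 12 alternatives; it lost the threshold with only the 15 longer genes (0.311, p = 0.543), an estimated correlation (0.595, p = 0.671) and the stricter filter (0.559, p = 0.103), was −0.069 with offsets, and ranged from −0.189 to 1.101 without a library. Mean replicate similarity (Spearman's rho 0.886) was 0.929 without a filter and 0.828 with the stricter one. Without a library the value was the rho of the single pair left within a group, from 0.882 to 0.911, and no mean. Of 51 values for the 4 named identifiers under alternatives, 43 stayed past 5% and 8 did not, all of them for the falling pair; with the replicate block ENSOCUG00000002481 had a log2 fold change of −6.07 (edgeR adjusted p = 0.14). At these depths and with 2 libraries per group, 0 of 50 simulated 2-fold changes were recovered in data drawn independently for each gene.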

Other observations

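The median span of the rising genes was 8.95 kb, against 56.8 kb for the falling genes and 23.1 kb for all tested genes (two-sided permutation test of rising against falling, p = 2e-05). Their median exon length was 1326 bases, against 2668 for the falling genes (p = 4e-05, same permutation test). Over all tested genes, the Spearman rho of span was −0.337 with the fold change and −0.346 with the difference between the 2 noPRP libraries. On 1 stretch of chromosome 13, positions 132920172 to 133017336, both tested genes rose, from 5.42 and 1.98 CPM to 2440 and 2470 CPM, of which 1 gene held at least 98.3% in each library; the other had 2 and 0 counts in noPRP and 353 and 739 in PRP. On chromosome 15, positions 76261876 to 76287475, 2 of 3 tested genes rose, from 16.1 and 49.6 CPM to 6290 and 2290 CPM. On chromosome 18, between positions 37228300 and 37356907, 2 of 4 tested genes fell, from 79.5 and 386 CPM to 3.04 and 3.59 CPM. These regions and the tests of span and exon length were chosen after the values were seen.

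The tests of swapped labels, of overlapping gene models and of the regional trend as the whole cause were chosen after the results were seen. Fold changes followed chromosomes and neighbouring genes. A regional bias that also separates libraries of one group may account for this trend, since adjacent genes had alike differences between the 2 noPRP libraries (Spearman's rho 0.425) and between the PRP libraries (0.2), and the noPRP difference rose with local gene density (rho 0.403) and fell with gene span (rho −0.346). These 2 properties go with base composition, which was not tested because no genome sequence was used, and a difference in state between cultures stays open. The other splits of the 4 libraries into pairs called 0 genes in edgeR (6 and 505 at an unadjusted p under 0.05) against 109. This argues against labels exchanged between 1 library of each group only if PRP gave the most consistent difference between libraries. Genes that separate the labelled groups widen the spread in the other splits. The split of noPRP replicate 1 with PRP replicate 2 had 41.9% of genes without overlap, near the 46.9% of the labelled split. A full exchange of the group labels gives the same split with signs reversed, so these counts cannot address it. Whether the trend was the whole cause of the called genes was not decided. With regional offsets the median log2 fold change went from 7.23 to 7.18 for rising and from −5.87 to −5.25 for falling genes. It kept at least 89.3% of its size. Past 5% stayed 46 of 68 and 12 of 41, with a prior of 7.24 in place of 11.43 degrees of freedom. The measure of size replaced a count of kept calls after 58 of 109 was seen. Called genes had log2 fold changes of at least 4.01 in size, and chromosome medians lay between −0.85 and 0.66. Offsets smoothed over neighbours could hardly remove such changes, and rho between neighbours fell only to 0.208. The values show only that the smoothed trend was small beside the called changes.

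Rising genes lay next to each other, 31 of 68. Gene-dense location alone is argued against, since 0 of 1000 draws matched on local gene density reached 31 (highest 18). These draws took genes independently. The difference between the 2 noPRP libraries was alike in adjacent genes (Spearman's rho 0.425) and rose with gene density (rho 0.403). The draws therefore cannot address a regional bias that follows gene density. Overlapping gene models that share reads had little room to act, since by the counting defaults reads on overlapping genes were dropped. The 11 groups also held an overlapping pair in 0 cases. That strongly differing genes of any of these libraries lie together is left open, since 16 of the 68 genes with the largest noPRP difference in one direction were grouped. Joint regulation of neighbouring genes or gene families by PRP is a candidate explanation that was not tested, because the identifiers carry no names. For the same reason, RNA of other cells was not tested as a source of the rising genes.

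Across genes, noPRP replicate 1 minus noPRP replicate 2 and PRP replicate 2 minus PRP replicate 1 had a Pearson r of 0.63, and 0.729 among the 4354 genes with an average log2 CPM of at least 5. Of 483 genes that differed by at least 2 on the log2 scale in both, 471 had the same sign, and 3 of these were among the called genes. The within-group difference had a Pearson r of 0.542 with the PRP effect across the tested genes. PRP replicate 1 minus noPRP replicate 1 had an r of 0.251 with PRP replicate 2 minus noPRP replicate 2. For PRP replicate 2 minus noPRP replicate 1 with PRP replicate 1 minus noPRP replicate 2 it was 0.748. Fold changes over all tested genes were thus not separate from the differences between replicates.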
